A study of Homo sapiens with 6 samples.

How the data were processed

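RNA-seq was run on the H9 line, an established human embryonic stem cell line, kept in PXGL medium and naive per the labels. Cells were transfected with 25 nM of a LINE-1 sense oligonucleotide (SO-L1, the control) or a LINE-1 antisense oligonucleotide (ASO-L1), and RNA was taken 48 hours later from unsorted cells, per the labels. LINE-1 elements are the autonomous retrotransposons still active in the human genome. For the first part of that time both arms also received trans-ISRIB, which blocks the output of the integrated stress response, the caspase inhibitor emricasan and a ROCK inhibitor. Libraries were made from poly(A)-selected RNA with a directional kit. There were 3 libraries in each of the 2 groups, and their titles number them 1 to 3 in both. Nothing in the labels says that replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

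The deposited count table holds raw read counts per gene symbol, and the authors' processing notes name Trim Galore 0.4.0, TopHat2 2.0.13, featureCounts and Subread 1.5.0 with the build hg19, without roles or order. Which annotation was used, whether reads were counted by strand and what the removal of duplicates named in the table's title covered are not given in the sources used here. Removing duplicates without molecular identifiers lowers the counts of abundant genes most. Where counting did not use strand, reads of a gene and of an overlapping antisense gene cannot be told apart. How reads from near-identical copies were assigned is likewise not stated. Values of histone, zinc finger, DUX4, RFPL4A, PRAMEF and TRIM43 genes, of pseudogenes and of nuclear copies of mitochondrial genes are therefore uncertain on this point. A deposited table of log2 normalised values, described by the authors as batch-corrected with a threshold of 0.2, was used only to see what the correction removed. In it the means of the 3 replicate numbers differed by a median of 0.0181 log2 units per gene, against 0.208 in log2 CPM computed here from the counts. The authors' deposited comparison table gives, per the file headers, a log2 fold change, a mean log2 expression, a moderated t score, a log-odds score, a p-value and an adjusted p-value for each of 20964 genes. Its model is not stated. Every gene in it reached a CPM of at least 0.205 in some library and no other gene exceeded 0.196, so its filter equals a CPM above 0.2 in at least 1 library.

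All tests here started from the counts. Genes were kept by filterByExpr of edgeR 4.0.16 with its defaults (minimum count 10, minimum total 15), which left 16873 of 53712 genes, and 20275 genes had no read in any library. Factors were TMM. The main test was the edgeR quasi-likelihood test with robust dispersion and no term for the replicate number, Benjamini-Hochberg adjusted, two-sided, with calls at an adjusted p under 0.05. A standard error is the unshrunken log2 fold change divided by the square root of the F statistic. CPM are TMM-normalised and given as mean ± SD over 3 libraries. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1, so none is reported for single genes. Library totals ran from 23330875 to 31164287 counts and the common biological coefficient of variation was 10.2%.

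Before the data were examined, 32 gene lists were written from general knowledge, and 31 had at least 5 tested members. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, adjusted over the 31 lists, and again with an estimated correlation and with fry. Also fixed then was the rule for named genes. It takes the 12 largest increases and the 12 largest decreases among called genes with an average log2 CPM of at least 1 and no overlap between the groups' libraries, leaving out unnamed clones, and 1 of these genes is not reported here. It adds up to 4 members with the smallest p of each list and any tested 8-cell gene. Any LINE-1 element in the table would have come first, but no line of it names one. Genes named outside this rule, in the closing part, were chosen after their values were seen.

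The replicate numbers were checked for pairing through the correlation of deviations from the group means. It was 0.102, 0.377 and 0.211 for numbers 1, 2 and 3, and they were taken as pairs. However, control library 1 correlated more with ASO-L1 library 3 (0.156), and ASO-L1 library 1 more with control library 3 (0.162). The correlations thus match only number 2 clearly and do not settle how numbers 1 and 3 pair. Values with the block and by pair rest on this choice. Values with the replicate number as a block are given beside a named gene or a list where the block changed its call or moved its count by more than 1.5 times. No pair of libraries within a group was alike within sampling noise, with a chi-square per degree of freedom of 2.05 for ASO-L1 replicates 1 and 3 and of 6.55 to 24.9 for the other pairs.

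Alternatives were the block, DESeq2 size factors, other filters (no filter, CPM above 0.2 or above 1 in 3 libraries), DESeq2 1.42.0, limma-voom, a test against a 1.2-fold change, other adjusted p thresholds, scaling without the 20 genes with the most counts, and leaving out each library or each replicate number. On counts simulated from the means and dispersions of these 16873 genes, 200 genes were changed. The test called 56.7% of those changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold. Of its calls 7.95% were unchanged genes. The adjusted p depends on the share of genes that change, and the real comparison called 5684 genes. The simulated shares therefore do not carry over to it. Gene span, transcript length and GC content in the closing part came from GENCODE annotation of a later genome build than the one the reads were aligned to, matched by symbol for 85.7% of tested genes, and no coordinates from it are given. R 4.3.3 was used.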

Results

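Poly(A) RNA of H9 cells, naive per the labels, was compared 48 hours after transfection with an antisense (ASO-L1) or a sense (SO-L1) LINE-1 oligonucleotide, with 3 libraries in each group. The SO-L1 libraries held 30956692, 24027869 and 30626711 counts for replicates 1 to 3, and the ASO-L1 libraries 24340574, 23330875 and 31164287. The study's title places the experiment in work on LINE-1 and PRC2 in nucleolar organisation and in repression of the 8-cell-like state, and the design has this 1 comparison. No line of the count table names a LINE-1 element, so the knockdown itself is not analysed here. The first principal component of log2 CPM held 68.8% of the variance and separated the groups, at -38.3, -21.3 and -40.5 for SO-L1 and 22.3, 58.9 and 18.9 for ASO-L1. Replicate 2 stood apart in both groups. Over the genes called below, the median absolute log2 difference within a replicate number was 0.425, 0.626 and 0.417 for numbers 1, 2 and 3.

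The largest increases after ASO-L1 were in genes with a low level in the control, from 0.0651 ± 0.0861 CPM (SD, n = 3) for SLAMF7 to 3.89 ± 2.66 CPM for DIO3. SLAMF7, a receptor of immune cells, rose to 9.09 ± 5.76 CPM, a log2 fold change of 7.17 ± 0.87 (SE), and DRGX, a homeobox gene of sensory neurons, from 0.179 ± 0.198 to 6.40 ± 4.68 CPM (5.24 ± 0.85). NPAS4, an activity-induced transcription factor, rose by 5.08 ± 0.83 on the log2 scale and EGR1, an immediate-early gene, by 3.31 ± 0.58. Transcription factor genes of developing tissues were also in this group, with 3.53 ± 0.71 for DLX2 and 3.32 ± 0.50 for SIX2. Other increases of the fixed set were XIRP1 (4.46 ± 0.52), CAMK2N1 (3.58 ± 0.33), DIO3 (3.56 ± 0.81), which encodes a deiodinase that inactivates thyroid hormone, ECM1 (3.49 ± 0.40) and KRT17 (3.36 ± 0.26). Adjusted p-values of these 11 genes ran from 5.25e-04 for KRT17 to 0.0265 for DIO3, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In each all ASO-L1 libraries lay above all SO-L1 libraries. Both the call and this separation were conditions of the fixed rule, so neither adds support for these genes. The call was lost for DIO3 without ASO-L1 replicate 1 (adjusted p = 0.0594) or SO-L1 replicate 3 (0.0681) and for DLX2 without SO-L1 replicate 3 (0.0507). With no filter DIO3 (0.0807) and DLX2 (0.0734) were lost, and without replicate 3 of both groups NPAS4 (0.0518), EGR1 (0.0550), DIO3 (0.140) and DLX2 (0.0627).

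Decreases were smaller. The chemokine receptor gene CCR8 fell from 3.57 ± 0.395 to 0.791 ± 0.353 CPM, a log2 fold change of -2.13 ± 0.28, and PLA2G2A, a secreted phospholipase, from 12.3 ± 0.204 to 3.75 ± 0.599 CPM (-1.71 ± 0.14). KHDC3L, an oocyte and early embryo gene counted among the naive markers, fell from 65.7 ± 12.9 to 25.0 ± 9.34 CPM (-1.39 ± 0.31). HES2 (-1.62 ± 0.15), GPX2 (-1.53 ± 0.21), a glutathione peroxidase, TMTC1 (-1.47 ± 0.14) and HOXB1 (-1.35 ± 0.18) fell from 10 CPM or more. FXYD4 (-1.65 ± 0.25), CLCA2 (-1.47 ± 0.28), TMEM179 (-1.46 ± 0.19), SCN3B (-1.39 ± 0.27) and the pseudogene HNRNPA1P21 (-2.04 ± 0.30) completed the 12, and how reads of the pseudogene and its parent gene were told apart is not stated. The call of KHDC3L was lost without ASO-L1 replicate 1 (adjusted p = 0.0533) or SO-L1 replicate 3 (0.0569), with no filter (0.101) and without replicate 1 (0.0551) or 3 (0.0873) of both groups, and that of CLCA2 without replicate 1 of both (0.0580).

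Across all 16873 tested genes, 5684 were called by edgeR, 3031 higher and 2653 lower after ASO-L1. At least 2-fold changes were found for 660 higher and 183 lower genes, so 78.3% of these were increases against 53.3% of all calls. The libraries of the groups did not overlap for 50.9% of tested genes. For a single gene chance gives 10%, but genes of the same 6 libraries are not independent, so the share is no test against chance. Without SO-L1 replicate 1 the count was 3166, without SO-L1 replicate 3 it was 2975, without replicate 1 or 3 of both groups it was 1183 or 2820, and a test against a 1.2-fold change called 2066.

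**Figure D1:**
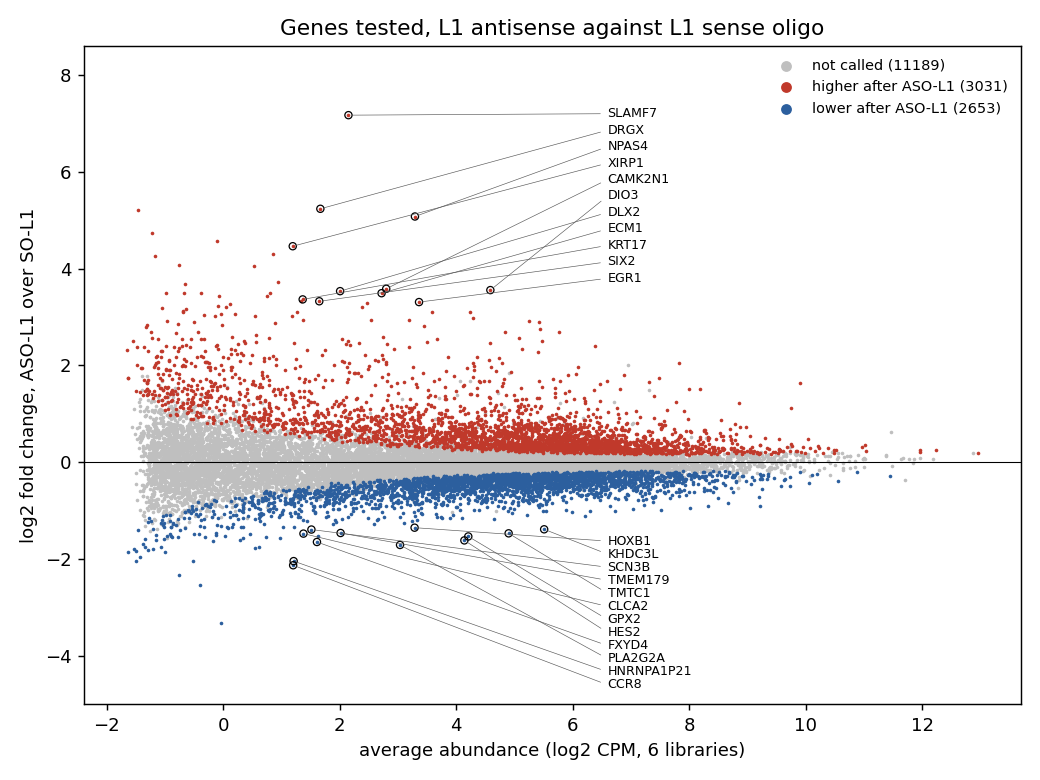
Log2 fold change of each tested gene (ASO-L1 over SO-L1, vertical axis) against its average log2 CPM over the 6 libraries (horizontal axis); each point is 1 gene, red if called higher (3031), blue if called lower (2653), grey otherwise, and the circled points are the 23 genes named from the fixed rule's largest changes. The largest increases, up to 7.17 for SLAMF7, exceed the largest decreases among the circled genes, down to -2.13 for CCR8.

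The 8-cell list asks whether genes of the 8-cell embryo and targets of the embryonic activator DUX4 went up with the antisense oligo. Of 46 genes written, 43 were in the table and 21 had enough counts to be tested. RFPL4A rose from 0.251 ± 0.104 to 1.14 ± 0.531 CPM (2.18 ± 0.45, adjusted p = 0.00551), SNAI1, better known as a regulator of epithelial-mesenchymal transition, from 11.3 ± 3.02 to 75.7 ± 52.6 CPM (2.74 ± 0.57, 0.0202), and ZNF280A from 0.446 ± 0.215 to 0.996 ± 0.0873 CPM (1.19 ± 0.36, 0.0268). The other 18 did not pass, among them ZSCAN4, a marker of the state, at 1.07 ± 0.454 and 0.584 ± 0.360 CPM (-0.85 ± 0.45, 0.163), TPRX1 (-0.44 ± 0.23, 0.172), TRIM43 (0.59 ± 0.33, 0.186), CCNA1 (0.36 ± 0.13, 0.0597) and PRAMEF12 (-0.85 ± 0.37, 0.0955). DUX4 had no counted read in any library, a value that depends on how reads of near-identical copies were assigned. LEUTX had 47 reads in all, of which the SO-L1 libraries held 7, 9 and 19 and the ASO-L1 libraries 1, 3 and 8.

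Adjusted over the list alone, 3 members rose as well. As a set the list did not differ from other genes by camera (adjusted p = 0.538, and adjusted p = 0.829 with an estimated correlation), with a median log2 fold change of 0.26. With the replicate block 4 members were higher and 1 lower, adding CCNA1 (0.00313) and PRAMEF12 (0.0476). Without SO-L1 replicate 1 (0.770) or ASO-L1 replicate 2 (0.916) the set test of the 8-cell and DUX4-target genes pointed downward. The called members numbered 5 without SO-L1 replicate 2 and 1 without SO-L1 replicate 3. SNAI1 was lost with no filter (0.0658), without SO-L1 replicate 3 (0.0577) and without replicate 3 of both groups (0.131). RFPL4A was lost without replicate 1 of both groups (0.0555), and ZNF280A without replicate 1 (0.172) or 3 (0.150) of both, and also without SO-L1 replicate 1 (0.106) or 3 (0.110) or ASO-L1 replicate 1 (0.0529) or 2 (0.0520). ZSCAN4 was called lower without ASO-L1 replicate 1 (0.0441), which had 0.991 CPM against 0.307 and 0.454 in ASO-L1 replicates 2 and 3. CCNA1 was called higher without SO-L1 replicate 2 (0.0322), with no filter (0.0198), by DESeq2 (0.0469) and without replicate 2 of both groups (0.00263), and PRAMEF12 lower without ASO-L1 replicate 3 (0.0479) and with no filter (0.0422).

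**Figure D2:**
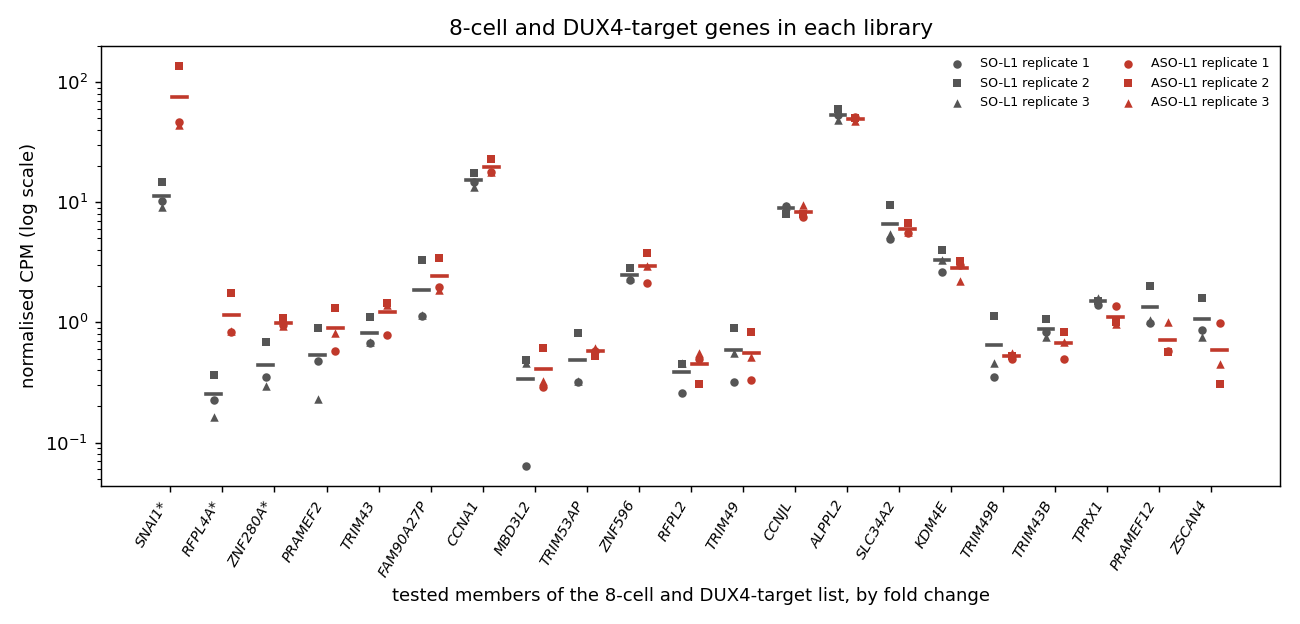
Normalised CPM (log scale, vertical axis) of the 21 tested 8-cell and DUX4-target genes (horizontal axis, ordered by fold change) in the 3 SO-L1 libraries (grey) and the 3 ASO-L1 libraries (red); symbols mark the replicate number, bars the group means, and asterisks the 3 genes called by edgeR. SNAI1 rose from a mean of 11.3 to 75.7 CPM, and ZSCAN4 overlapped between the groups.

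Pluripotency genes moved in both directions among the naive markers. FGF4 fell from 41.8 ± 3.76 to 20.1 ± 4.84 CPM (-1.06 ± 0.16) and DPPA3, a maternal factor of the early embryo, from 17.4 ± 0.861 to 9.38 ± 2.33 (-0.88 ± 0.16). SUSD2, a surface marker of naive cells (-0.52 ± 0.10), and DNMT3L (-0.47 ± 0.09) fell too. Of 26 tested naive markers 4 rose and 7 fell (5 and 8 adjusted over the list alone, 6 and 10 with the block), and the set test gave an adjusted p of 0.167. In the core list only PRDM14 was called, at -0.39 ± 0.08, among 16 members (1 adjusted over the list alone). With the replicate block 9 of the 16 were lower, NANOG (-0.28 ± 0.10, adjusted p = 0.0553 without and 0.00396 with the block) and TERF1 (-0.52 ± 0.18, 0.0615 and 7.94e-06) among them. Camera's adjusted p for the core list went from 0.0641 to 0.0349, with adjusted p = 0.723 with an estimated correlation, or 0.730 with both. The core list also passed camera with no filter (0.0211) and without ASO-L1 replicate 1 (0.0464), ASO-L1 replicate 3 (0.0401) or SO-L1 replicate 2 (0.0289). NANOG passed without ASO-L1 replicate 1 (0.0316), with no filter (0.00295) and by DESeq2 (0.0425). TERF1 passed without SO-L1 replicate 2 (0.0396) or ASO-L1 replicate 2 (0.0180), by DESeq2 (0.00319) and by limma-voom (0.0251). Primed markers were mixed, 5 higher and 2 lower of 23 (the same counts adjusted over the list alone, 7 and 6 with the block), led by the intermediate filament gene VIM (1.24 ± 0.13) and the surface antigen gene THY1 (0.51 ± 0.09). Their median was -0.03, their mean 0.17, and camera pointed upward with an adjusted p of 0.568. Leaving out replicate 1 of both groups ended the calls of DPPA3 (0.0609), DNMT3L (0.0732) and PRDM14 (0.0762). Leaving out replicate 2 of both brought calls of NANOG (0.00772) and TERF1 (1.86e-09) and of the core list (0.0466).

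Some markers of other lineages rose, several of them from low levels. In the trophectoderm and trophoblast list 9 of 21 rose and 1 fell (9 and 1 adjusted over the list alone), with DLX5 going from 0.181 ± 0.0957 to 3.56 ± 2.66 CPM (4.29 ± 0.70), CDX2 from 0.369 ± 0.142 to 1.80 ± 1.29 (2.24 ± 0.54) and the keratin gene KRT8 from 1054 ± 18.6 to 1323 ± 131 (0.33 ± 0.07). The fibroblast and mesenchymal list had 7 of 16 higher and 1 lower (7 and 1 adjusted over the list alone), with TAGLN at 1.32 ± 0.15 and TWIST1 at 2.47 ± 0.49. Both lists were called higher by camera (adjusted p = 0.0292 and 0.0339), and both were lost with an estimated correlation (adjusted p = 0.723 with an estimated correlation for each). Of 11 germ layer genes 4 rose and 1 fell (4 and 1 adjusted over the list alone). PAX6 (1.74 ± 0.24) and LHX2 (2.17 ± 0.47) were higher and SOX21 (-1.21 ± 0.17) lower, and the list had an adjusted p of 0.0641 by camera and 0.0296 with the block, a call lost with an estimated correlation (adjusted p = 0.723 with an estimated correlation, 0.730 with the block as well). Primitive endoderm had 5 higher and 1 lower of 15 (5 and 1 adjusted over the list alone), BMP2 (1.14 ± 0.23), AFP (0.98 ± 0.24) and CER1 (2.29 ± 0.42) among those that rose, and camera gave 0.303. Amnion markers had 3 higher and 1 lower of 8 (3 and 2 adjusted over the list alone, and also with the block), HEY1 at 2.59 ± 0.46 and IGFBP5 at -0.95 ± 0.21, with an adjusted p of 0.295.

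In these lineage lists the calls of CDX2 (0.0570) and TWIST1 (0.0537) were lost without SO-L1 replicate 3. Without replicate 1 of both groups CDX2 (0.0502), KRT8 (0.0532), LHX2 (0.0778) and IGFBP5 (0.0530) were lost, and without replicate 3 of both groups KRT8 (0.0565), TWIST1 (0.130), AFP (0.0840) and CER1 (0.0843). With no filter TWIST1 (0.0591) and HEY1 (0.0515) were lost. The trophectoderm list lost its call without SO-L1 replicate 1 (0.105) or ASO-L1 replicate 2 (0.120), with no filter (0.0526) and with a CPM above 1 in 3 libraries (0.0540), and the fibroblast list without the same libraries (0.105 and 0.0738). Leaving out replicate 1 of both groups ended the call of the trophectoderm list too (0.0845). The germ layer list passed without replicate 2 of both groups (0.0466), with no filter (0.0253) and without SO-L1 replicate 2 (0.0282) or ASO-L1 replicate 3 (0.0382).

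Among HOX genes HOXC13 rose by 2.18 ± 0.54 and HOXB1 fell, with 2 higher and 2 lower of 12 (2 and 2 adjusted over the list alone, 6 and 3 with the block). Camera gave an adjusted p of 0.403 (adjusted p = 0.804 with an estimated correlation and all libraries). It gave 0.00655 with no filter. Without SO-L1 replicate 2 it gave 0.00713, but there the filter, applied anew, kept 17 HOX genes rather than 12. HOXC13 was lost without SO-L1 replicate 3 (0.0591). In the germ cell list TDRKH fell by 0.52 and DMRT1 rose by 1.94 ± 0.53, the only calls among 10 (1 and 1 adjusted over the list alone, 1 and 4 with the block). The list had an adjusted p of 0.124, and DMRT1 was lost without SO-L1 replicate 1 (0.0691) or 3 (0.0845). Of 4 tested cancer-testis antigens, too few for a set test, MAGEB4 was called lower (-1.84 ± 0.64), though not when adjusted over the list alone. Its call was lost without SO-L1 replicate 1 (0.103) or 2 (0.0866), or without ASO-L1 replicate 2 (0.102) or 3 (0.142), and DESeq2 did not call it (0.0854). Without ASO-L1 replicate 1 the cancer-testis list had 5 tested members, 2 of them called lower. Camera then called the list lower (adjusted p = 0.0264), which was not tried with an estimated correlation. The calls of TDRKH (0.0593) and DMRT1 (0.0893) were lost without replicate 1 of both groups, of MAGEB4 (0.0623) without replicate 2 of both and of DMRT1 (0.111) without replicate 3 of both.

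Changes among the genes of Polycomb repressive complex 2 (PRC2) were small. Of 12 PRC2 subunits and partners 2 rose and 3 fell (4 and 5 adjusted over the list alone, 4 and 5 with the block). EZH2, the catalytic subunit, went from 73.0 ± 3.10 to 59.2 ± 8.47 CPM (-0.30 ± 0.10, adjusted p = 0.0407), the cofactor AEBP2 changed by -0.32 ± 0.08 (0.0111), RBBP4 by -0.24 ± 0.07 and PHF19 by 0.27 ± 0.07. The set's median was -0.06, its mean was above 0 at 0.005, and camera pointed downward with an adjusted p of 0.80. Without single SO-L1 libraries the call of EZH2 was lost (adjusted p = 0.142, 0.0540 and 0.116 without replicates 1, 2 and 3), that of RBBP4 without replicates 1 (0.0719) and 3 (0.0823), and that of PHF19 without replicate 3 (0.0749). AEBP2 was lost without replicate 1 (0.0995) or 3 (0.0623) of both groups. PRC1 subunits held larger changes, 8 higher and 2 lower of 21 (8 and 3 adjusted over the list alone), with PCGF1 going from 8.98 ± 2.11 to 30.5 ± 9.66 CPM (1.77 ± 0.25), PHC2 up by 0.88 ± 0.18 and CBX7 at -1.11 ± 0.19, and the set at 0.216. In the list of DNA methylation, H3K9 methylation and repeat silencing 5 rose and 5 fell of 34 (4 and 5 adjusted over the list alone, 6 and 10 with the block). The H3K9 methyltransferase gene SUV39H1 rose by 0.57 ± 0.09 and SAMHD1, a restriction factor for retroelements, went from 255 ± 9.80 to 152 ± 27.7 CPM (-0.75 ± 0.12), with the set at 0.514. ZNF-named zinc finger genes, many of them KRAB-type repressors of retroelements, had 140 higher and 48 lower of 486 (146 and 49 adjusted over the list alone), with the smallest p-values for ZNF567 (1.05 ± 0.11), ZNF486 (-0.63 ± 0.08) and ZNF436 (2.21 ± 0.27). That set was called higher (adjusted p = 0.0129) with a median of 0.13, but not with an estimated correlation (adjusted p = 0.723 with an estimated correlation) and not without SO-L1 replicate 1 (0.0747). The calls of EZH2 (0.164), RBBP4 (0.131), PHF19 (0.0890), PHC2 (0.0532), CBX7 (0.0577) and SUV39H1 (0.0554) also ended without replicate 1 of both groups, and those of EZH2 (0.10), RBBP4 (0.117) and PHF19 (0.174) without replicate 3 of both.

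Part of the genes for ribosome production rose, by small amounts. RRN3, the initiation factor of RNA polymerase I, went from 67.7 ± 2.24 to 108 ± 11.8 CPM (0.68 ± 0.08), PES1 from 214 ± 4.66 to 283 ± 18.9 (0.40 ± 0.06) and NOP56 from 201 ± 4.86 to 282 ± 33.3 (0.49 ± 0.08). In the nucleolus and ribosome biogenesis list 18 of 44 rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.16. Cytosolic ribosomal protein genes had 19 higher and 5 lower of 82 and a median of 0.13, but adjusted over the list alone only the 2 decreases of RPL26 (-0.36 ± 0.08) and of RPS27L (-0.30 ± 0.07), a paralog that p53 induces, were called. RPL30 (0.31 ± 0.08) was the increase with the smallest p. With the block 31 rose and 5 fell. Both lists were called higher by camera (adjusted p = 0.0129 and 0.00949) and neither with an estimated correlation (adjusted p = 0.723 with an estimated correlation for each). Without SO-L1 replicate 2 the ribosomal protein list lost its call (0.0558), and RPL30 lost its own without SO-L1 replicate 3 (0.0594). With both libraries of replicate 1 left out RPL26 (0.0892), RPS27L (0.115) and RPL30 (0.0560) were lost, with those of replicate 2 the ribosomal protein list (0.216), and with those of replicate 3 RPL30 (0.0643) and the ribosome biogenesis list (0.0513).

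The mitotic genes KIF2C (0.64 ± 0.08), CDCA8 (0.71 ± 0.10) and PLK1 (0.42 ± 0.06) rose with 17 of 30 members of the G2 and M list, while 3 fell (18 and 4 adjusted over the list alone, 18 and 5 with the block). The list was called higher (adjusted p = 0.0130; adjusted p = 0.723 with an estimated correlation). In S phase 11 rose and 4 fell of 32 (11 and 4 adjusted over the list alone, 13 and 8 with the block), E2F8 by 1.06 ± 0.12, SLBP by 0.57 ± 0.09 and CCNE2 by 1.77 ± 0.30, and the list was not called (0.114). Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had 7 higher of 32 (4 adjusted over the list alone, 11 with the block). HIST3H2A rose by 0.92 ± 0.22 and HIST2H2BE by 1.60 ± 0.35, and the list had an adjusted p of 0.0129 (adjusted p = 0.723 with an estimated correlation). The G2 and M list lost its call without SO-L1 replicate 2 (0.0945). It was also lost without replicate 2 of both groups (0.0622), and HIST3H2A without replicate 1 of both (0.0517).

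Targets of p53 fell or did not pass. TNFRSF10B, a death receptor gene, went from 105 ± 17.5 to 51.8 ± 2.44 CPM (-1.02 ± 0.11), FDXR from 78.2 ± 5.12 to 53.5 ± 2.45 (-0.55 ± 0.07) and ZMAT3 from 64.4 ± 10.9 to 41.5 ± 1.78 (-0.63 ± 0.11). In all 14 of 27 targets were lower while the other 13 did not pass (14 adjusted over the list alone). Camera called the list lower (adjusted p = 0.0222; adjusted p = 0.723 with an estimated correlation). With the block 7 were higher and 15 lower and the call was lost (0.0616), as it was without ASO-L1 replicate 1 (0.0505). Cholesterol synthesis genes fell in 10 of 24 cases (11 lower and 1 higher adjusted over the list alone, 12 and 1 with the block). STARD4 fell by 0.35 and LSS fell by 0.36. The list was called lower (adjusted p = 0.0292; adjusted p = 0.723 with an estimated correlation), though not without SO-L1 replicate 1 (0.0777) or 3 (0.0596). Omitting replicate 1 of both groups ended the calls of STARD4 (0.0802) and LSS (0.107) and of the cholesterol list (0.102), which omitting replicate 3 of both ended too (0.0513).

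Stress genes were mixed in direction. Of 28 genes of the integrated stress and unfolded protein responses 10 rose and 3 fell (11 and 3 adjusted over the list alone). The stress transcription factor ATF4 went from 317 ± 20.7 to 512 ± 95.4 CPM (0.69 ± 0.12) and its target MTHFD2 rose by 0.31 ± 0.06, while SLC7A11 (-0.64 ± 0.11) and DDIT4 (-0.47 ± 0.09) fell. The list was called higher (adjusted p = 0.0263; adjusted p = 0.723 with an estimated correlation), but not without SO-L1 replicate 1 (0.0777), SO-L1 replicate 3 (0.0677) or ASO-L1 replicate 2 (0.0738). Heat shock genes had 6 higher and 1 lower of 13 (7 and 1 adjusted over the list alone), DNAJA1 at 0.47 ± 0.09 and HSPA4L at -0.69 ± 0.13, with the list at 0.114. Interferon and innate immunity genes had 4 higher and 3 lower of 27 (4 and 3 adjusted over the list alone). IFI27 (3.01 ± 0.43) and IRF1 (1.15 ± 0.17) were up and BST2 (-1.11 ± 0.15), which encodes tetherin, and STAT2 (-0.41 ± 0.09) down. The list stood at 0.768 upward, or 0.964 downward without ASO-L1 replicate 2. When replicate 1 of both groups was left out MTHFD2 (0.0562), DDIT4 (0.0887), STAT2 (0.0621) and HSPA4L (0.0563) were lost, and when replicate 3 of both was left out MTHFD2 (0.0554) and STAT2 (0.0536) and the integrated stress list (0.0524).

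In the list around oligonucleotide uptake, RNase H and paraspeckles, MALAT1, a nuclear non-coding RNA, rose by 0.48 ± 0.07, NONO by 0.17 ± 0.06 and SFPQ by 0.18 ± 0.06. The other 7 of 10 did not pass (3 adjusted over the list alone, 4 higher and 1 lower with the block). The list's median was 0.03, its mean -0.002 and camera's adjusted p 0.564 upward. NONO and SFPQ lost their calls without SO-L1 replicate 1 (0.0871 and 0.111), 2 (0.0985 and 0.0648) or 3 (0.0905 and 0.117), and without ASO-L1 replicate 1 (0.0983 and 0.0967) or 3 (0.122 and 0.153). They were also lost with no filter (0.127 and 0.103). Decay and splicing factors had 8 higher and 1 lower of 26 (9 and 1 adjusted over the list alone, 10 and 2 with the block), with TRA2B at 0.32 ± 0.06 and SRSF6 at 0.27 ± 0.06. Camera gave an adjusted p of 0.131, or 0.723 with an estimated correlation, and fry gave 3.20e-05. Adhesion and epithelial genes had 6 lower and 1 higher of 15 (7 and 3 adjusted over the list alone, 7 and 3 with the block), CDH1, which encodes E-cadherin, at -0.46 ± 0.09, ITGA6 at -0.59 ± 0.12 and OCLN at 0.58 ± 0.13, with the list at 0.191. Glycolysis and hypoxia genes had 3 higher and 5 lower of 25 (4 and 6 adjusted over the list alone, 5 and 11 with the block), PFKL at -0.42 ± 0.09 and PFKP at -0.49 ± 0.11, with the list at 0.303, and at 0.0483 without replicate 2 of both groups (adjusted p = 0.775 with an estimated correlation and all libraries). Nuclear oxidative phosphorylation genes had 4 higher and 8 lower of 77 (1 and 4 adjusted over the list alone, 8 and 17 with the block), NDUFB8 at -0.48 ± 0.09 and NDUFB9 at -0.41 ± 0.09, with the list at 0.124, and at 0.0133 without SO-L1 replicate 2 (adjusted p = 0.804 with an estimated correlation and all libraries). Of 13 mitochondrially encoded genes MT-ND1 (0.31 ± 0.08) and MT-ND2 (0.36 ± 0.10) rose (2 adjusted over the list alone), with the list at 0.295, and at 0.0172 without SO-L1 replicate 3 (adjusted p = 0.804 with an estimated correlation and all libraries). Both genes were lost without SO-L1 replicate 1 (0.0828 and 0.0881) or 2 (0.0593 and 0.0608) or ASO-L1 replicate 3 (0.0554 and 0.0547). Further calls lost without replicate 1 of both groups were those of NONO (0.192), SFPQ (0.223), TRA2B (0.0616), SRSF6 (0.0764), CDH1 (0.0579), ITGA6 (0.0573), OCLN (0.0756), PFKL (0.0923), PFKP (0.0799), NDUFB8 (0.0703), NDUFB9 (0.0757), MT-ND1 (0.167) and MT-ND2 (0.158). Calls lost without replicate 3 of both were those of NONO (0.234), SFPQ (0.316) and SRSF6 (0.0648), and without replicate 2 of both the oxidative phosphorylation list passed (0.0188).

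In all, camera called 8 lists higher and 2 lower of 31, and 9 higher and 2 lower with the block. None was called with an estimated correlation, where the number at an unadjusted p under 0.05 was also 0. By fry 2 lists moved one way on balance, ribosome biogenesis (0.0140) and the decay and splicing factors, and 26 held genes that changed in either direction. Of the 10 lists called by camera, only ribosome biogenesis and the histones kept the call without each single library in turn, and ribosome biogenesis lost it without replicate 3 of both groups (0.0513). Without SO-L1 replicate 1 camera called 5 lists, 4 higher and 1 lower. Without ASO-L1 replicate 2 it called 5 higher, without SO-L1 replicate 2 it called 4 lower and without SO-L1 replicate 3 it called 1 lower.

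**Figure D3:**
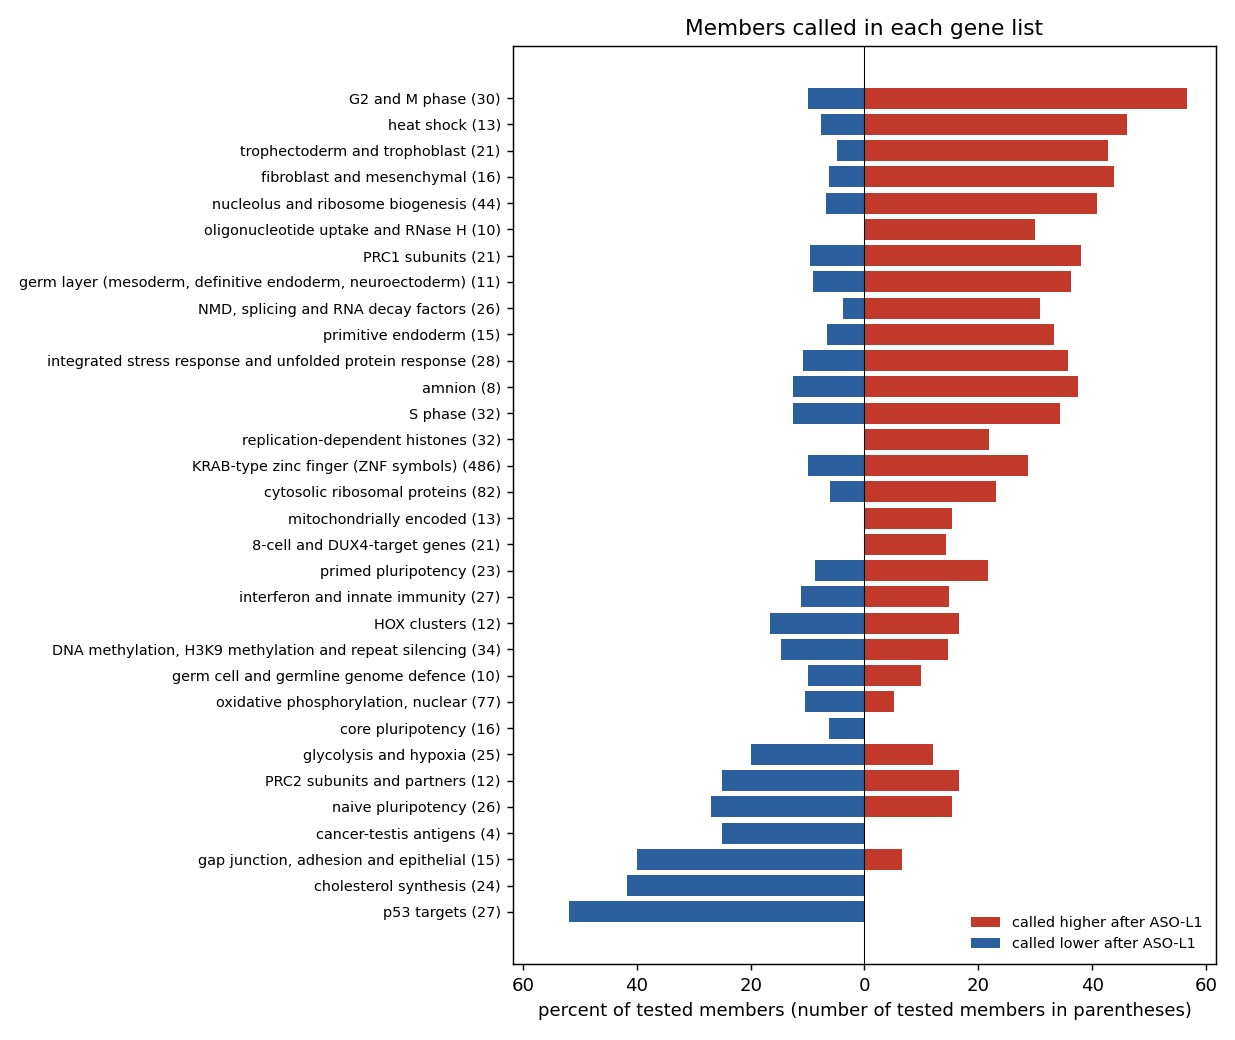
Percent of tested members called higher (red, to the right) or lower (blue, to the left) after ASO-L1 in each of the 32 gene lists (vertical axis, number of tested members in parentheses; horizontal axis in percent). The G2 and M list has the most members called higher relative to its size (17 of 30), and the p53 targets the most called lower (14 of 27).

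The counts were last set against the authors' deposited table of the same comparison, which rests on the same libraries and so is no independent evidence. The authors' deposited table has 4493 genes at an adjusted p under 0.05, 2444 higher and 2049 lower. Of the 5684 genes called here 4284 were also called in the authors' deposited table, all with the same sign, and 1459 shared calls would be expected of independent lists. The table's other 46 calls among the 16873 genes tested in both were not called here, and 1400 genes were called here only. Log2 fold changes in the authors' deposited table correlated with those computed here at r = 0.998 across genes, which are not independent replicates. Its t statistics correlated at 0.997 with a limma-voom fit without the block and at 0.957 with the block, but those fits called 5512 and 7817 genes, so neither is the authors' exact model.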

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

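For the counts of genes and the named genes, scaling without the 20 genes with the most counts was chosen after seeing the data, as were the alternatives for the overlap with the authors' deposited table, and the other alternatives, including this scaling for the gene lists, were chosen before. DESeq2 size factors, DESeq2, limma-voom and a CPM above 0.2 in 3 libraries left every gene count of the comparison within 1.5 times, and the scalings moved no list's direction. With the replicate block 5 8-cell genes were called, 1 of them lower, and 1 was lower with no filter. With the block edgeR called 7719 genes in all, 3931 higher and 3788 lower. DESeq2 called 5664 with the block and 5431 without it. Among the named genes and the set tests of the lists, the block changed no other call than those given with them. Of the 43 8-cell genes counted, 21 had enough counts to be tested. A CPM above 1 in 3 libraries left 111 genes at least 2-fold lower and 1 8-cell gene, higher, since fewer genes were tested. A test against a 1.2-fold change gave 2066 genes, 1261 higher and 805 lower, and an adjusted p under 0.01 gave 2460, 1377 higher and 1083 lower, both stricter by construction. Camera with an estimated correlation called 0 lists, 0 higher and 0 lower, with 0 at an unadjusted p under 0.05, and fry called 2, 2 higher and 0 lower. Leaving out 1 library or 1 replicate number gave 1183 to 7197 genes (757 to 3726 higher, 426 to 3471 lower), 439 to 1024 at least 2-fold (360 to 833 higher, 79 to 234 lower), 1 to 5 8-cell genes (1 to 5 higher, 0 to 1 lower), 5 to 12 lists (4 to 9 higher, 1 to 5 lower) and 1176 to 4313 genes shared with the authors' table. Without replicate 1 fewer samples leave less power, but the count without replicate 2 rose above that of all 6 libraries, and the cause was not tested. The direction of the 8-cell set test, not past its threshold in any setting, turned with no filter (adjusted p = 0.892), without replicate 1 (0.842), SO-L1 replicate 1 (0.770) or ASO-L1 replicate 2 (0.916), in a range of 0.0621 to 0.916 when samples were left out. That of the interferon list turned without ASO-L1 replicate 2 (0.964), in a range of 0.415 to 0.964, and the cause was not tested. Of 121 named genes 59 kept their direction and side of the threshold under every alternative, and over all alternatives 1903 comparisons were unchanged, 20 gained the call, 0 turned and the rest lost it. Of the 113 called among them, 45 lost the call without replicate 1 of both groups, 1 without replicate 2 and 23 without replicate 3. Of 31 lists 12 kept theirs, and 461 comparisons were unchanged, 42 lost and 18 gained the call and 5 turned.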

Other observations

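The gene classes and genes of the next paragraphs were chosen after the results were seen, as were the tests of a background of reads, of the TOP class, of members under 1 log2 CPM and of slopes by pair. The other tests were set before their own result was seen.

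Immediate-early genes, transcribed within minutes of a stimulus, rose after ASO-L1 in 32 of 44 cases and fell in 1. Their median log2 fold change was 1.39 (unadjusted p = 0.239 by camera with an estimated correlation). The class shares EGR1 and NPAS4 with the largest increases and CYR61 and CTGF with the fibroblast list. ATF3 and PPP1R15A are also in the integrated stress list, so these rises are not separate findings. EGR3 went from 0.516 ± 0.223 to 4.44 ± 2.81 CPM (3.11 ± 0.54, n = 3, edgeR), EGR2 from 0.508 ± 0.150 to 4.15 ± 2.61 (3.02 ± 0.49), JUNB from 17.6 ± 1.89 to 46.0 ± 15.3 (1.39 ± 0.22) and FOSB from 3.09 ± 1.24 to 10.4 ± 4.58 (1.76 ± 0.37). The call of FOSB was lost without replicate 1 of both groups (0.0563). KLF17, a marker of the naive state that the labels give for these cells, had 0.743 ± 0.196 CPM in the control. After ASO-L1 it had 0.395 ± 0.146 CPM (adjusted p = 0.103, edgeR). It is 1 of 26 tested naive markers, and others, such as KHDC3L at 65.7 ± 12.9 CPM, were higher in the control. Whether so low a level of KLF17 bears on the label was not tested.

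Host genes of small nucleolar RNAs rose in 14 of 16 cases and fell in 1, at a median of 0.79 (unadjusted p = 0.178 with an estimated correlation). SNHG1 went from 150 ± 20.7 to 430 ± 77.9 CPM (1.52 ± 0.14), SNHG15 rose by 1.29 ± 0.21 and GAS5 by 1.07 ± 0.23, while SNHG14 changed by -0.29 ± 0.09. The call of GAS5 was lost with no filter (0.0814) and SNHG14 without SO-L1 replicate 1 (0.0693) or 3 (0.121), or without replicate 1 (0.106) or 3 (0.107) of both groups. Trends with transcript length, GC content and abundance left a median residual of 0.71, and the class lay 0.65 above ribosomal protein genes. The class was chosen after its rise was seen, so neither value decides against those trends or a rise of the TOP transcripts as a class. Ribosomal protein genes, the TOP transcripts compared, had a lower median of 0.13, at percentile 99.95 of random lists. Camera with an estimated correlation gave them an unadjusted p of 0.546. What the removal of duplicates did to such abundant genes is not known. Percentiles of random lists compare genes with other genes and do not measure the spread between libraries. Weaker nonsense-mediated decay may contribute, but the median of 19 other decay targets, 3 higher and 1 lower, lay at percentile 83.9 of random lists. For these targets fry gave an unadjusted p of 0.0119 and camera with an estimated correlation 0.224. SRSF6, UPF1 and others of them are also in the list of decay and splicing factors, so they are not a separate set. Weaker decay stays open.

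Genes of developmental transcription factor families rose in 51 of 109 cases and fell in 4. Their median was 1.13 (unadjusted p = 0.248 by camera with an estimated correlation). The class shares DLX5, CDX2, TWIST1, PAX6 and LHX2 with the lineage lists above, and DRGX, DLX2 and SIX2 with the largest increases. These rises are therefore not separate findings. Members under 0 log2 CPM exceeded other genes that low by 1.49 (95% interval 1.08 to 2.03, over genes and not libraries). The median residual after the property trends was 0.90. Both values were bound to be high in a class picked for its rise. They therefore do not decide against a background of genomic or unspliced reads or against the trends. The 2399 other genes under 0 log2 CPM had a median of 0.07, so genes that low did not rise as a whole. The median of 68 members under 1 log2 CPM lay at percentile 100 of random lists, but the class was chosen because its members rose, so this decides nothing and a rise of regulators as a class stays open.

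Genes with a long genomic span were lower, and in the longest of 10 groups of protein-coding genes the median was -0.27, with 4.78% higher and 32.5% lower, against 0.07, with 313 higher and 142 lower of 1361, in the shortest, and the slope was -0.06 per doubling. With transcript length, GC content and abundance in the model 126% of the slope was left, and 69.1% without genes changed at least 2-fold, which speaks against those trends and against short strongly changed genes as the whole cause. The groups' slopes did not overlap, with a gap of 0.687 of the larger range within a group, and ASO-L1 minus SO-L1 was -0.0387, -0.0828 and -0.0578 for replicate numbers 1 to 3. All 3 pairs went one way, but an exact sign-flip test of 3 pairs cannot give a two-sided p below 0.25, so a drift between libraries could also give it and cannot be told apart. LINE-1 content of introns was not analysed here.

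The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 5684 genes, 843 at least 2-fold and 3 8-cell genes, against 0, 0 and 0 by edgeR as the highest of the other splits, where 79 to 918 genes had an unadjusted p under 0.05 and limma-voom called 0. For each of these 1 split, the real one, gave a result as large. Every other split put libraries of both groups on each side, so a difference between the groups widened the spread within each side. Few calls were therefore bound to come from those splits, and they cannot serve as a measure of chance for these counts. For lists 5 splits, the real one among them, gave at least as many as the real 10, with 13 as the highest of the others. Among the others that part all replicate pairs the highest was 6. The number of lists called by camera with its preset correlation therefore does not set the real split apart from all others.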
